A study of Mus musculus with 18 samples.

How the data were processed

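Gene expression was measured by sequencing of poly(A) RNA from RAW264.7 cells, a mouse macrophage-like line. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with the NEBNext Ultra II RNA kit. The 18 libraries formed 6 groups of 3: cells given a control guide RNA and cells of a line made deficient in Kdm7a with CRISPR/Cas9, each left unstimulated (M0) or put under M1 or M2 conditions for 48 h. Groups and replicate numbers came from the sample titles, and each column was matched to its sample through the library name in the labels. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Only 1 knockout line and 1 control line were named. Differences between these lines that do not come from Kdm7a thus cannot be told apart from knockout effects in any comparison of genotypes.

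The deposited values are TPM, transcript shares scaled to a fixed total, that the authors computed per gene symbol, with 2 decimals and the same total in each library. The name of the table speaks of both raw counts and TPM, and the values are not whole numbers, so they were treated as TPM. Trim Galore (no version) and the mm10 build are named per the submitters' processing notes. The aligner, the quantification tool and the gene annotation are not given in the sources used here. Because TPM keeps no depth, the depth of each library is unknown, and no counting interval or detection limit was computed. TPM are shares of a fixed total: a strong rise of some genes lowers the values of all others. How reads shared by gene copies were assigned is likewise unknown, so values of close paralogs, such as the histone, MHC, ribosomal protein and Ccl3 and Ccl4 genes, are uncertain.

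The table held 24411 gene symbols, of which 7246 were listed at 0 in every library. Of all symbols, 23194 matched a symbol in a mouse RefSeq gene table for the same build. Members of the gene lists were also sought by synonym, but gene positions came from matched symbols only. Some symbols are older ones, such as Irg1 for Acod1. No gene of the mitochondrial genome was among the symbols analysed. An entry of 0 can be a failed estimate: 2 of 109 ribosomal protein and oxidative phosphorylation genes, Ndufs5 and Rpl26, were at 0 in some libraries. For a gene listed at 0 in any library of a group, the values of the libraries are given in place of a mean. No 2 libraries of the 153 pairs held identical values.

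Tests used limma-trend with robust variance moderation on log2(TPM + 1), in one model with a mean for each of the 6 groups. All groups share the variance estimate of a gene, so libraries outside a comparison also enter its p-value. The 11548 genes at 1 TPM or more in at least 3 libraries were tested. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, and the number with a change of 2-fold or more was also counted. The tests are two-sided. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The 9 comparisons were M1 and M2 stimulation in each genotype, the knockout in each of 3 conditions, and the difference between genotypes in the response to M1 and to M2. The tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. They foresaw raw counts first, and the test on log2(TPM + 1) was the branch set down for a table with TPM only.

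Gene lists came from general knowledge of macrophages and of this line. Of 27 lists, 24 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over all 216 list tests. Of these tests, 112 passed, and 30 of them also passed with a correlation estimated from the data. Numbers of called members were adjusted over all tested genes, and again over the list alone.

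The genes named in the text follow a fixed rule. They are Kdm7a; in each comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 TPM in the higher group and no overlap between the libraries compared, unnamed gene models left out (for the differences between responses, overlap was allowed); the markers Nos2, Il6, Tnf, Il1b, Cxcl10, Cd86, Arg1, Mrc1, Chil3, Retnla, Ccl22 and Il10, called or not; and up to 4 called members with the largest changes from each list that passed camera, and always from the M1-associated, M2-associated and interferon-stimulated lists. Genes named outside it in the results are said to be so.

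The alternatives were trimmed-mean (TMM) factors computed on the TPM scale, limma without the mean-variance trend, no filter, a filter of 5 TPM, a replicate block, a pseudocount of 0.1 TPM, a fit of only the groups compared, and each library left out in turn. For the lists they were an estimated correlation and limma's fry. A scaling by median ratios, the scaling alternatives for the lists, and a fit without 2 libraries were added after the data had been seen. These were M2 control library 2 and M1 knockout library 3, which held unexpected transcripts at low levels. An alternative that needs raw counts was not run.

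The test was tested on simulated data for the knockout comparison without stimulation. These were built from the means of all groups and the spread within groups over all 18 libraries. Noise was drawn independently for each gene from a normal distribution, with the same spread in every group. How the test behaves where the spread of a gene differs between groups was thus not tested. Changed genes were drawn only among those with an unstimulated control mean above 2 on the log2(TPM + 1) scale. Recovery of lower genes was not tested. Among 11548 genes, it recovered 34 of 50 genes changed by 0.25 on the log2 scale, 49 of 50 changed by 0.5, 50 of 50 changed by 1 and 49 of 50 changed by 2, and called 12 of 11348 unchanged genes. A simulated rise of 0.5 in the cholesterol synthesis list was called, and 0 other lists of the 24 were. Because the noise was independent between genes, this does not show how the list test behaves where members vary together. R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9 were used.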

Results

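The libraries described the transcriptome of RAW264.7 cells, a line of mouse macrophages, with and without Kdm7a, a histone demethylase of the Jumonji family that removes methyl groups from lysines 9 and 27 of histone H3 and lysine 20 of histone H4. The series asked how loss of this enzyme alters the transcriptome during macrophage polarization. Cells with a control guide RNA and Kdm7a-deficient cells were left unstimulated (M0) or were given interferon gamma at 2 ng/ml with bacterial lipopolysaccharide at 0.1 µg/ml (M1). Others were given the cytokines IL-4, IL-10 and IL-13 at 20 ng/ml with human TGF-beta 1 at 2 ng/ml (M2). Each condition lasted 48 h. Each of the 6 groups had 3 libraries, so every mean ± SD below has n = 3. The deposited unit was TPM, and sequencing depth was unknown. Of the control groups, on average 10731 genes stood at 1 TPM or more without stimulation, 10437 under M1 and 10858 under M2, and 10752, 10338 and 10812 in the knockout groups. The 10 most abundant genes took 6.85 ± 0.12% of all TPM in unstimulated control cells, 10.9 ± 0.046% under M1 and 6.71 ± 0.13% under M2.

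Libraries of one group correlated across genes at r = 0.994 to 0.997, against 0.985 to 0.991 between knockout and control libraries of the same condition. Between M1 and unstimulated control libraries r was 0.721 to 0.731, and between M2 and unstimulated ones 0.953 to 0.955 (genes are not independent replicates). The first principal component held 84.6% of the variance and parted the M1 libraries from all others, and the second, with 10.2%, parted M2 from unstimulated libraries.

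**Figure D1:**
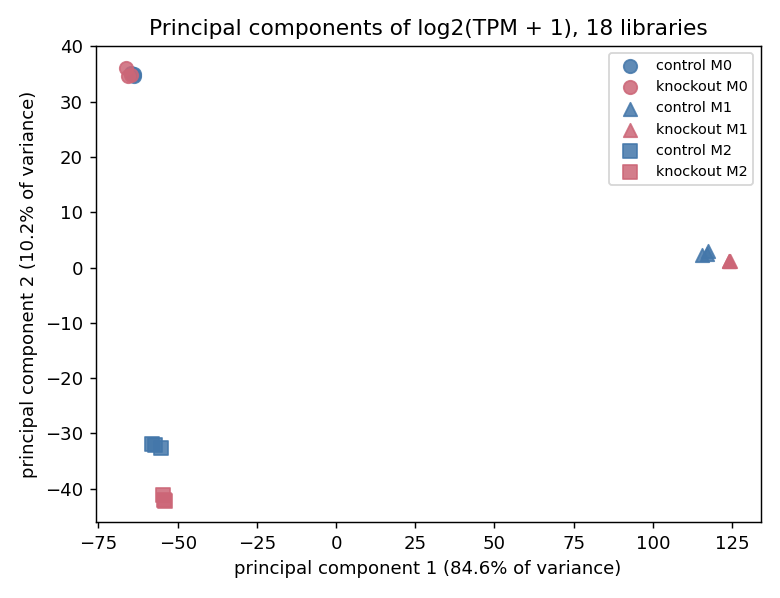
Principal components of log2(TPM + 1) for the 18 libraries over the 11548 tested genes, component 1 (84.6% of the variance) against component 2 (10.2%), with 1 point per library and colours and shapes for genotype and condition. M1 libraries stand apart along component 1 and M2 libraries along component 2, with the 3 libraries of each group close together.

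Kdm7a, on chromosome 6 at 39136620 to 39206773 of the GRCm38 build, was lower in every knockout library than in every control library of its condition. Without stimulation it stood at 11.1 ± 0.17 TPM in control and 3.37 ± 0.14 TPM in knockout cells, under M1 at 29.7 ± 0.85 TPM and 7.49 ± 0.26 TPM, and under M2 at 23.3 ± 1.1 TPM and 6.80 ± 0.88 TPM. The knockout groups thus kept 30.3%, 25.3% and 29.2% of the control level of this transcript. On the log2 scale Kdm7a fell by 1.47, 1.85 and 1.65 (limma adjusted p = 5.43e-12, 4.36e-14 and 6.05e-13). A frameshift made by Cas9 need not remove the transcript, so mRNA levels do not measure the remaining protein. In control cells Kdm7a itself rose with stimulation, by 1.34 log2 units under M1 and by 1.01 under M2 (limma adjusted p = 1.36e-13 and 1.06e-10).

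**Figure D2:**
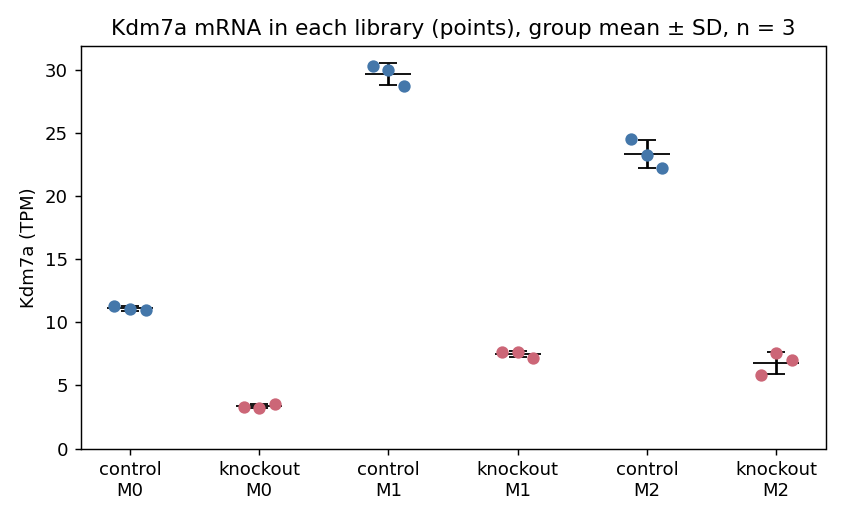
Kdm7a level in TPM in each of the 18 libraries, by condition and genotype, with points for libraries and bars for the group mean ± SD. Control groups average 11.1, 29.7 and 23.3 TPM at M0, M1 and M2, and knockout groups 3.37, 7.49 and 6.80 TPM.

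Under M1 stimulation of control cells Ptgs2, which encodes the inducible cyclooxygenase, rose from 0.713 ± 0.67 to 7890.4 ± 136 TPM, the chemokine gene Ccl5 from 4.01 ± 0.68 to 15289 ± 63 TPM. Nos2, which encodes the inducible nitric oxide synthase, rose from 0.430 ± 0.15 to 3572 ± 55 TPM. The cytokine gene Il6 rose to 1550.2 ± 59 TPM and was at 0, 0 and 0.19 TPM in the 3 libraries without stimulation, and Tnf rose from 73.7 ± 1.5 to 2147 ± 28 TPM. Genes of dividing cells moved the other way: Ccna2, which encodes cyclin A2, fell from 265.1 ± 9.3 to 0.437 ± 0.14 TPM, and Rrm2, a subunit of ribonucleotide reductase, from 205 ± 5.1 to 0.897 ± 0.14 TPM. Limma gave Ptgs2 a log2 fold change of 12.24 ± 0.57 (SE, adjusted p = 1.05e-10) and Ccna2 one of -7.54 ± 0.072 (adjusted p = 7.35e-25).

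Among the fixed lists, of 29 M1-associated genes 28 rose and 1 fell (camera adjusted p = 4.10e-13, or 0.00551 with an estimated correlation). Of the 48 interferon-stimulated genes 48 rose (camera adjusted p = 9.86e-23, or 0.0409 with an estimated correlation). The antiviral gene Rsad2 rose from 2.06 ± 0.57 to 5171 ± 178 TPM and the guanylate-binding protein gene Gbp5 from 0.143 ± 0.093 to 924 ± 26 TPM. All 25 NF-kappaB feedback and target genes rose (camera adjusted p = 5.39e-13, or 0.00551 with an estimated correlation), with the chemokine gene Cxcl2 at 3.64 ± 0.10 TPM and 3337 ± 78 TPM. Of 19 genes for presentation on MHC class I, 18 rose and 1 fell (camera adjusted p = 1.76e-09, or 0.00315 with an estimated correlation), and with TMM scaling 19 rose. Tap1, a subunit of the peptide transporter, rose from 24.9 ± 2.0 to 401 ± 2.7 TPM. All 36 cell cycle genes fell (camera adjusted p = 6.16e-10, or 0.00315 with an estimated correlation), Ube2c from 359 ± 5.9 to 1.70 ± 0.49 TPM and Birc5 from 266 ± 7.7 to 1.41 ± 0.20 TPM. For each of these 5 lists the numbers were the same adjusted over the list alone.

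Metabolic lists passed camera at its preset correlation and lost the call with an estimated one. Of 22 cholesterol synthesis genes 1 rose and 21 fell (camera adjusted p = 2.42e-04, or 0.190 with an estimated correlation), Fdps, which makes farnesyl diphosphate, from 883 ± 14 to 99.6 ± 2.7 TPM. Of 21 glycolysis genes 17 rose, 2 fell and 2 were not called (camera adjusted p = 1.52e-05, or 0.214 with an estimated correlation). The glucose transporter gene Slc2a1 rose from 141 ± 6.1 to 1174 ± 15 TPM. Of 64 oxidative phosphorylation genes 1 rose, 62 fell and 1 was not called (camera adjusted p = 6.14e-08, or 0.145 with an estimated correlation). Of 44 ribosomal protein genes 44 fell (camera adjusted p = 3.77e-08, or 0.205 with an estimated correlation), Rpl3 from 2793 ± 23 to 591 ± 8.1 TPM. Under TMM scaling 6 oxidative phosphorylation genes rose and 56 fell, and 2 ribosomal protein genes rose and 41 fell. Lysosomal genes mostly rose, 24 of 29 against 4 that fell (camera adjusted p = 3.56e-07, or 0.145 with an estimated correlation), and so did 11 of 16 NRF2 targets (camera adjusted p = 0.00159, or 0.196 with an estimated correlation). The heme oxygenase gene Hmox1, an NRF2 target, rose from 108 ± 2.8 to 2003 ± 72 TPM. Numbers adjusted over the list alone were the same for these 6 lists.

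In total 10290 of 11548 genes changed between unstimulated and M1 control cells, 3716 higher and 6574 lower, with 1681 and 3567 by 2-fold or more. The share of higher genes, 36.1%, depended on the scaling: it was 53.2% with TMM factors, under which 2711 genes were higher and 2300 lower by 2-fold or more. The median log2 fold change of all tested genes was -0.38, and 0.084 with TMM factors, so changes in M1 cells stood against that shift.

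M2 stimulation of control cells raised a smaller set of genes. Arg1, which encodes arginase 1 and is the classical marker of IL-4-treated mouse macrophages, rose to 1876 ± 58 TPM and was at 0.34, 0 and 0.07 TPM in the 3 libraries without stimulation. Cish and Socs1, which encode feedback inhibitors of cytokine signalling, rose from 0.06, 0.14 and 0 TPM in the 3 libraries to 137 ± 6.3 TPM and from 0.567 ± 0.045 to 105 ± 5.1 TPM. Id1, a target of TGF-beta family signalling, rose from 0.797 ± 0.20 to 161 ± 6.9 TPM, and Anxa8 to 157 ± 7.7 TPM and was listed at 0 in all 3 libraries without stimulation. The lymphotoxin beta gene Ltb fell from 130.4 ± 8.0 to 1.11 ± 0.56 TPM, the prostaglandin-degrading enzyme gene Hpgd from 132 ± 14 to 3.30 ± 0.66 TPM, and Tnf from 73.7 ± 1.5 to 11.02 ± 1.1 TPM. Chil3 and Retnla, often used as M2 markers, were listed at 0 in all 18 libraries, Ccl22 was listed at 0 in all control libraries without stimulation and under M2, and Il10 was not called (limma adjusted p = 0.715).

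Of 24 M2-associated genes 20 rose and 4 were not called (20 and 1 adjusted over the list alone, camera adjusted p = 1.40e-11, or 0.00551 with an estimated correlation). Tgm2, which encodes transglutaminase 2, rose from 1.80 ± 0.21 to 78.3 ± 7.9 TPM. Of 21 targets of TGF-beta and SMAD proteins 19 rose and 2 fell (camera adjusted p = 2.66e-10, or 0.0390 with an estimated correlation), Pmepa1 from 0.0967 ± 0.071 to 67.0 ± 1.4 TPM. Genes for presentation on MHC class II rose, 10 of 13 with 3 not called (camera adjusted p = 6.80e-07, or 0.00551 with an estimated correlation). Ciita, the master regulator gene of this set, rose from 0.0700 ± 0.010 to 28.3 ± 0.80 TPM. Of 36 cell cycle genes 34 fell and 2 were not called (camera adjusted p = 1.75e-07, or 0.00551 with an estimated correlation). Ccnd1 fell from 233 ± 1.8 to 129 ± 2.4 TPM. Interferon-stimulated genes fell in 25 of 48 cases and rose in 6 (camera adjusted p = 0.0353, or 0.616 with an estimated correlation). Oas3 fell from 22.8 ± 0.66 to 6.30 ± 0.54 TPM. For the last 4 lists the numbers adjusted over the list alone were the same.

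Lists of lipid, lysosomal and glycolytic genes moved up at the preset correlation only. Of 18 LXR target and lipid-handling genes 13 rose, 4 fell and 1 was not called (camera adjusted p = 5.79e-04, or 0.120 with an estimated correlation). The scavenger receptor gene Cd36 rose from 0.21, 0.24 and 0.45 TPM in the 3 libraries to 32.4 ± 2.5 TPM. Of 29 lysosomal genes 21 rose, 6 fell and 2 were not called (camera adjusted p = 7.61e-05, or 0.205 with an estimated correlation). Of 21 glycolysis genes 15 rose, 2 fell and 4 were not called (camera adjusted p = 6.79e-06, or 0.205 with an estimated correlation). Of 16 HIF targets 11 rose and 5 were not called (camera adjusted p = 3.04e-04, or 0.214 with an estimated correlation). Numbers adjusted over the list alone were the same for these 4 lists. The 29 M1-associated genes had no common direction (13 rose, 9 fell and 7 were not called, the same adjusted over the list alone; camera adjusted p = 0.498). The second M2 control library held M1 genes at a median of 0.153% of their M1 level. Nos2 stood at 2.04, 5.24 and 0.23 TPM in the 3 M2 libraries (limma adjusted p = 0.0487). Its call was lost without M2 library 1 or 2 (adjusted p = 0.105 and 0.228) or any 1 unstimulated library (0.0686 to 0.107), and in 5 other alternatives, over a range of 0.0531 to 0.251. Ptgs2, also called, stood at 6.62, 15.9 and 1.08 TPM (adjusted p = 0.00872, and 0.126 when only these groups were fitted).

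In total 7557 genes changed between unstimulated and M2 control cells, 3279 higher and 4278 lower. By 2-fold or more, 627 were higher and 196 lower. The share of higher genes was 43.4%, and 52.1% with TMM factors.

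**Figure D3:**
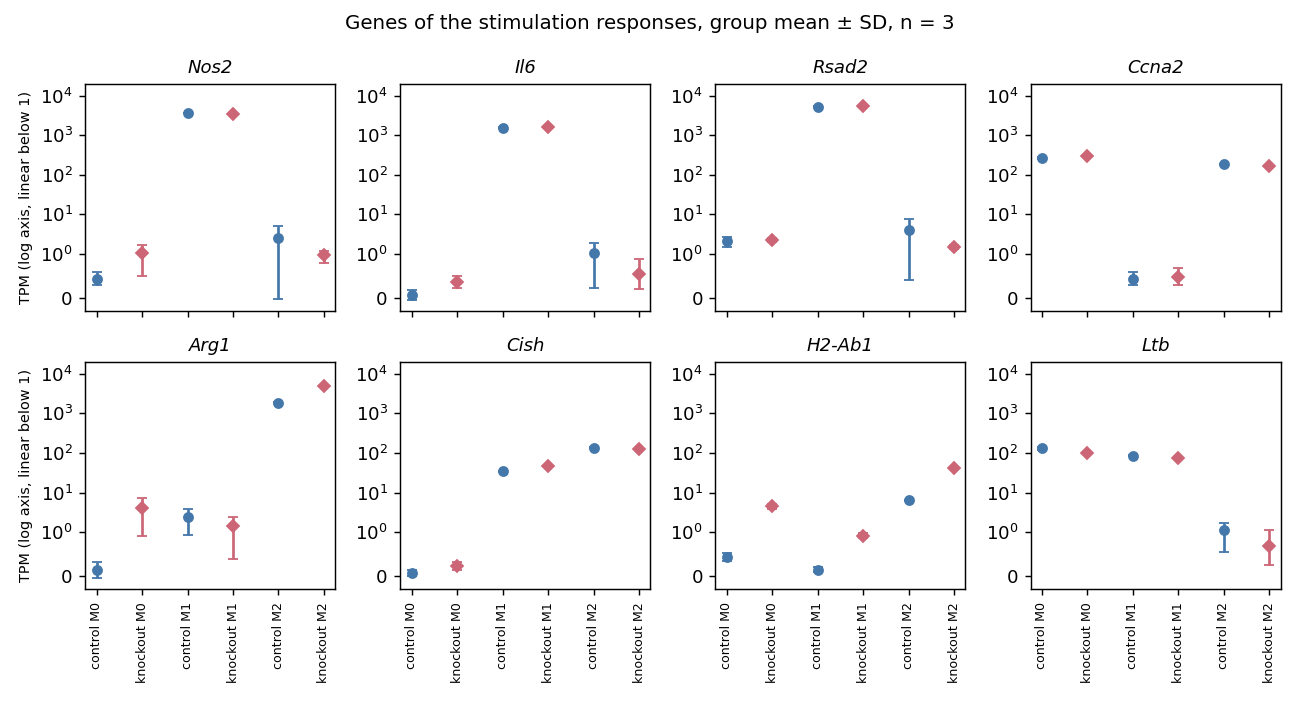
Group means ± SD (n = 3 libraries) in TPM of 8 genes at M0, M1 and M2, on a log axis that is linear below 1 TPM, with circles for control and diamonds for knockout cells. Nos2, Il6 and Rsad2 stand at 3572, 1550.2 and 5171 TPM in control cells under M1 and Arg1 at 1876 TPM under M2, while Ccna2 falls below 1 TPM under M1 in both genotypes.

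Knockout cells without stimulation differed from control cells in a limited set of genes with large changes. The protocadherin gene Pcdh7 rose from 1.21 ± 0.10 to 22.1 ± 0.58 TPM, Qprt, an enzyme of NAD synthesis, from 3.35 ± 0.94 to 28.5 ± 2.7 TPM. The aldo-keto reductase gene Akr1c12 rose from 1.56 ± 0.67 to 15.1 ± 0.48 TPM and the chemokine receptor gene Cxcr4 from 3.11 ± 0.13 to 12.2 ± 1.4 TPM. The homeobox gene Rhox5 fell from 71.9 ± 1.5 to 0, 0.12 and 0.28 TPM in the 3 libraries, the receptor gene Gpr34 from 92.3 ± 6.6 to 2.90 ± 0.35 TPM, and the scavenger receptor gene Msr1 from 12.4 ± 0.83 to 1.11 ± 0.26 TPM. The costimulatory molecule gene Cd86 fell from 11.7 ± 0.90 to 2.997 ± 0.040 TPM (log2 fold change -1.67 ± 0.065, limma adjusted p = 3.71e-13). Of the other fixed markers, Nos2, Il6, Tnf, Il1b, Mrc1, Ccl22 and Il10 were not called, though Mrc1 was called as higher without the variance trend (adjusted p = 0.0149) and with a pseudocount of 0.1 TPM (0.0108). Cxcl10 fell from 3.98 ± 0.35 to 3.17 ± 0.60 TPM (limma adjusted p = 0.0307), a call lost without control library 1 or 3 or knockout library 2 (adjusted p = 0.0965, 0.117 and 0.183) and in 2 other alternatives (0.0620 and 0.145). Arg1 was at 0.34, 0 and 0.07 TPM in control and 0.59, 4.83 and 6.58 TPM in knockout cells without stimulation, called at adjusted p = 0.0272. This call was lost when only these 2 groups were fitted (adjusted p = 0.131) or when control library 2 or 3 or knockout library 2 or 3 was left out (adjusted p = 0.0809, 0.0755, 0.0957 and 0.115).

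The list with the lowest camera p was that of the integrated stress response and unfolded protein response, of whose 19 genes 15 fell and 4 were not called, the same adjusted over the list alone (camera adjusted p = 1.47e-17, or 0.00154 with an estimated correlation). Ddit3, which encodes the stress-induced factor CHOP, fell from 122 ± 2.3 to 65.0 ± 0.33 TPM, the chaperone-associated gene Creld2 from 224 ± 10.2 to 139 ± 1.9 TPM and the secreted stress factor gene Manf from 237 ± 3.1 to 153 ± 4.2 TPM. Of 20 p53 targets 2 rose, 9 fell and 9 were not called (2 and 10 adjusted over the list alone, camera adjusted p = 0.00159, or 0.0259 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a fell from 224 ± 9.4 to 157 ± 11 TPM. Of 19 MHC class I presentation genes 8 rose, 1 fell and 10 were not called (10 and 2 adjusted over the list alone, camera adjusted p = 6.17e-04, or 0.0304 with an estimated correlation). The immunoproteasome gene Psmb9 rose from 58.3 ± 1.6 to 86.0 ± 5.3 TPM. Of 16 HIF targets 10 rose and 6 were not called (12 and 0 adjusted over the list alone, camera adjusted p = 1.99e-05, or 0.190 with an estimated correlation). Of 29 lysosomal genes 3 rose, 13 fell and 13 were not called (4 and 14 adjusted over the list alone, camera adjusted p = 0.00118, or 0.306 with an estimated correlation). The protease gene Ctsl fell from 217 ± 4.1 to 162 ± 0.29 TPM. The M1-associated list did not pass the test (2 rose, 5 fell and 22 were not called, the same adjusted over the list alone; camera adjusted p = 0.671). Nor did the M2-associated list, of which 6 rose, 3 fell and 15 were not called (8 and 5 adjusted over the list alone, camera adjusted p = 0.661).

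Between knockout and control cells 2217 of 11548 genes differed without stimulation, 1023 higher and 1194 lower in knockout cells. By 2-fold or more only 51 were higher and 52 lower.

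Under M1 stimulation some genes were higher and others lower in knockout than in control cells. The chemokine gene Ccl22 rose from 5.01 ± 0.94 to 47.4 ± 0.90 TPM, Tnfrsf9, which encodes the costimulatory receptor CD137, from 40.3 ± 1.1 to 238 ± 3.4 TPM, and the chemokine receptor gene Ccr7 from 11.4 ± 0.56 to 41.0 ± 2.8 TPM. The monocyte chemokine gene Ccl2 fell from 114 ± 7.2 to 8.89 ± 1.1 TPM and Il1rn, which encodes the antagonist of the interleukin 1 receptor, from 319.5 ± 12 to 29.8 ± 1.6 TPM. Il1b rose from 337 ± 14 to 806 ± 8.8 TPM. Tnf fell from 2147 ± 28 to 1542 ± 21 TPM and Cd86 from 219 ± 8.3 to 100.3 ± 2.3 TPM. Cxcl10 fell from 942 ± 13 to 812 ± 17 TPM (limma adjusted p = 0.0401), a call lost without any 1 of these 6 libraries and in 6 other alternatives, TMM factors among them (adjusted p = 0.0565 to 0.164 over the 12). Nos2, at 3572 ± 55 TPM in control and 3446 ± 54 TPM in knockout cells, and Il6, at 1550.2 ± 59 TPM and 1599 ± 23 TPM, were not called (limma adjusted p = 0.937 and 0.908), though Nos2 was at adjusted p = 0.0357 when only the M1 groups were fitted. The rise of Il1b, with a log2 fold change of 1.26 and adjusted p = 2.20e-05, kept that size with a pseudocount of 0.1 TPM, 1.26, but not the call (adjusted p = 0.132).

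Genes of antigen presentation on MHC class II were higher in knockout cells under M1, with 6 of 13 that rose and 7 not called (camera adjusted p = 3.10e-04, or 0.0304 with an estimated correlation). The invariant chain gene Cd74 rose from 837 ± 20.2 to 1719.8 ± 61 TPM. Of 36 cell cycle genes 2 rose, 22 fell and 12 were not called (camera adjusted p = 2.71e-04, or 0.0315 with an estimated correlation). Ccnb1, which encodes cyclin B1, fell from 2.88 ± 0.63 to 0.590 ± 0.36 TPM, at levels already low under M1. Of 16 NRF2 targets 3 rose, 12 fell and 1 was not called (camera adjusted p = 2.96e-04, or 0.145 with an estimated correlation). The peroxiredoxin gene Prdx1 fell from 7417 ± 156 to 2913 ± 81 TPM and Hmox1 from 2003 ± 72 to 1144 ± 5.3 TPM. Of 29 lysosomal genes 4 rose, 21 fell and 4 were not called (camera adjusted p = 1.04e-05, or 0.198 with an estimated correlation). Gpnmb fell from 433 ± 4.9 to 103 ± 1.6 TPM. Of 16 HIF targets 13 rose and 3 were not called (camera adjusted p = 1.52e-08, or 0.0917 with an estimated correlation). The vascular growth factor gene Vegfa rose from 348 ± 9.0 to 612 ± 5.8 TPM. Of 22 cholesterol synthesis genes 13 rose, 1 fell and 8 were not called (camera adjusted p = 4.09e-05, or 0.147 with an estimated correlation). The interferon-stimulated genes did not pass (6 rose, 12 fell and 30 were not called; camera adjusted p = 0.845). The test pointed upward, with a median of -0.035 and a mean of -0.027, and a median of 0.03 under TMM scaling. The M1-associated genes did not pass either (10 rose, 11 fell and 8 were not called; camera adjusted p = 0.444), tested upward with a median of 0.056 and a mean of -0.10. Numbers adjusted over the list alone were the same for all 8 lists. The third of these knockout libraries held 16 coding genes at 1 TPM or more that were listed at 0 in the other 2, against at most 3 such genes in any other library.

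In total 5811 genes differed between knockout and control cells under M1, 1954 higher and 3857 lower, with 99 and 135 by 2-fold or more. The share of higher genes was 33.6%, and 48.2% with TMM factors.

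Knockout cells under M2 stimulation carried more transcripts for MHC class II than control cells. H2-Ab1 and H2-Aa, which encode the chains of the I-A molecule, rose from 6.31 ± 0.34 to 41.3 ± 2.4 TPM and from 9.76 ± 0.83 to 37.3 ± 4.2 TPM, and H2-Eb1 from 3.79 ± 0.29 to 14.3 ± 0.32 TPM. Of the 13 tested genes of this list 9 rose and 4 were not called, the same adjusted over the list alone (camera adjusted p = 2.21e-08, or 0.00359 with an estimated correlation). Flt1, which encodes a receptor for vascular endothelial growth factor, rose from 11.5 ± 0.69 to 56.7 ± 5.8 TPM and Tgm2 from 78.3 ± 7.9 to 349.7 ± 36 TPM. Cd86 fell from 5.36 ± 0.57 to 1.27 ± 0.11 TPM, the interferon-induced chemokine gene Cxcl10 from 7.10 ± 0.16 to 2.24 ± 0.33 TPM and the purinergic receptor gene P2ry12 from 11.4 ± 0.56 to 0.210 ± 0.14 TPM. Arg1 stood at 1876 ± 58 TPM in control and 5070.2 ± 137 TPM in knockout cells. Its log2 fold change of 1.43 was not called in the model of all groups (limma adjusted p = 0.0599) and was called when only the M2 groups were fitted (adjusted p = 4.09e-09). The model of all groups shares the variance of a gene over all conditions, so the spread of Arg1 at low TPM without stimulation enters the first p-value.

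Of 24 M2-associated genes 10 rose, 4 fell and 10 were not called (11 and 5 adjusted over the list alone, camera adjusted p = 0.00786, or 0.198 with an estimated correlation). Interferon-stimulated genes fell in 21 of 48 cases and rose in 2 (2 and 23 adjusted over the list alone; camera adjusted p = 3.49e-05, or 0.327 with an estimated correlation). Usp18 fell from 15.7 ± 0.48 to 8.49 ± 0.29 TPM and Irf7, a transcription factor of the interferon response, from 17.7 ± 2.2 to 10.4 ± 1.2 TPM. M2 control libraries 1, 2 and 3 held M1 genes at a median of 0.0788%, 0.153% and 0.00853% of their M1 level, against 0.0210% to 0.0359% in M2 knockout libraries. Without control library 2 and M1 knockout library 3 the interferon list was at camera adjusted p = 0.00356 here. Of 36 cell cycle genes 1 rose, 23 fell and 12 were not called (1 and 25 adjusted over the list alone, camera adjusted p = 1.52e-05, or 0.0124 with an estimated correlation), and with TMM factors 1 rose and 15 fell. These falls were small: Cdk1 fell from 102 ± 3.1 to 79.0 ± 4.3 TPM. Of 29 lysosomal genes 14 rose, 4 fell and 11 were not called (15 and 4 adjusted over the list alone, camera adjusted p = 0.00177, or 0.311 with an estimated correlation). The acid lipase gene Lipa rose from 520.1 ± 6.8 to 838 ± 9.0 TPM, and Gpnmb fell from 111 ± 3.0 to 52.0 ± 2.6 TPM. Of 21 glycolysis genes 15 rose, 1 fell and 5 were not called, the same adjusted over the list alone (camera adjusted p = 2.59e-06, or 0.198 with an estimated correlation). In the p53 target list 1 rose, 11 fell and 8 were not called (3 and 13 adjusted over the list alone, camera adjusted p = 0.0437, or 0.145 with an estimated correlation). The death receptor gene Fas was the member that rose, from 10.8 ± 1.0 to 29.5 ± 1.5 TPM.

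In total 3570 genes differed under M2, 1462 higher and 2108 lower, with 92 and 59 by 2-fold or more. The share of higher genes was 41.0%, and 55.02% with TMM factors.

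**Figure D4:**
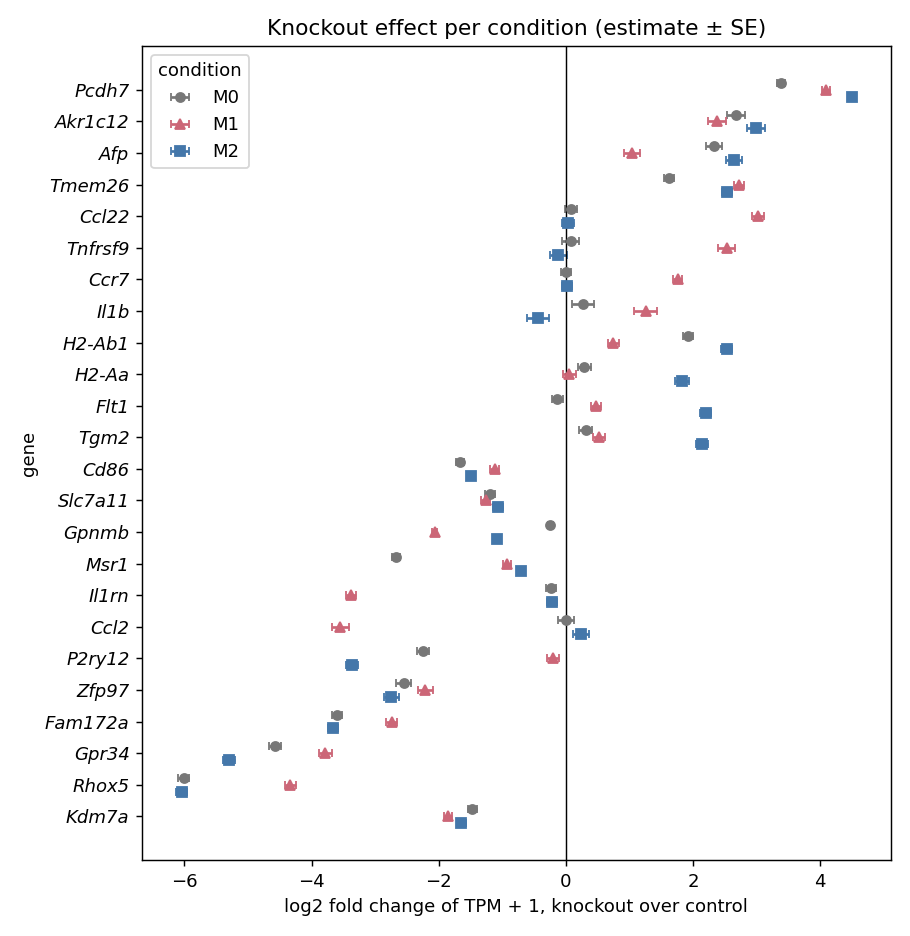
Log2 fold change ± SE of knockout against control cells on the log2(TPM + 1) scale for 24 genes at M0, M1 and M2 (limma, n = 3 libraries per group). Pcdh7 stands at 3.39, 4.10 and 4.51 and Rhox5 at -6.01, -4.33 and -6.04 at M0, M1 and M2, whereas Ccl22 reaches 3.02 at M1 against 0.078 and 0.028 at M0 and M2.

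Across the 11548 genes the 3 knockout effects, which share no library, were moderately correlated (genes are not independent replicates): r = 0.397 between M0 and M1, 0.570 between M0 and M2 and 0.359 between M1 and M2, with Spearman's rho of 0.280, 0.354 and 0.270. Between M0 and M2, 457 genes were higher in both and 613 lower in both, against 129.5 and 218.0 for independent sets of calls, and 170 were called in opposite directions. Between M0 and M1 these numbers were 422 and 710, against 173.1 and 398.8, with 289 opposite, and between M1 and M2 they were 567 and 1071, against 247.4 and 704.1, with 543 opposite. No number for independent sets was computed for opposite calls, so those counts alone do not show contrary effects. Calls in the 3 conditions also share the variance estimate of each gene, so they are not fully independent. Called in all 3 conditions in the same direction were 260 higher and 418 lower genes, of which 19 and 21 changed by 2-fold or more in each. Pcdh7, Akr1c12 and Rhox5 were among these, at log2 fold changes of 3.39, 4.10 and 4.51 for Pcdh7, 2.68, 2.38 and 2.996 for Akr1c12 and -6.01, -4.33 and -6.04 for Rhox5.

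Knockout cells responded to stimulation with largely the genes that responded in control cells. Under M1, Nos2 rose from 1.08 ± 0.58 to 3446 ± 54 TPM and Il1b from 0.25, 0.49 and 0.16 TPM in the 3 libraries to 806 ± 8.8 TPM in knockout cells, and Ccna2 fell from 293 ± 5.3 to 0.483 ± 0.19 TPM. All 48 interferon-stimulated genes rose (camera adjusted p = 1.01e-22, or 0.0412 with an estimated correlation) and all 36 cell cycle genes fell (camera adjusted p = 1.01e-09, or 0.00315 with an estimated correlation). Of 29 M1-associated genes 28 rose and 1 fell (camera adjusted p = 4.10e-13, or 0.00551 with an estimated correlation). Under M2, Arg1 rose to 5070.2 ± 137 TPM and Tgm2 from 2.51 ± 0.57 to 349.7 ± 36 TPM. Of 24 M2-associated genes 20 rose, 1 fell and 3 were not called (camera adjusted p = 9.07e-11, or 0.00551 with an estimated correlation). Of 13 MHC class II presentation genes 10 rose, 2 fell and 1 was not called (camera adjusted p = 2.25e-06, or 0.00551 with an estimated correlation), with 10 higher and 0 lower under TMM scaling. For these lists the numbers were the same adjusted over the list alone. In total 10430 genes changed under M1 (3691 higher, 6739 lower) and 8414 under M2 (3423 higher, 4991 lower). The shares of higher genes were 35.4% and 40.7%, and 52.8% and 50.7% with TMM factors. Across genes the responses of the genotypes correlated at r = 0.980 for M1 and 0.935 for M2 (Spearman's rho 0.973 and 0.908). Of 5248 genes changed 2-fold or more by M1 in control cells 5220 were called in the same direction in knockout cells, and of 823 for M2 809 were.

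The size of the response nevertheless differed for many genes, by the test of the difference itself. This difference equals the knockout effect under stimulation minus that without stimulation, so it can come from either. For M1 this held for 4161 genes, 1399 with a response that was more positive in knockout cells and 2762 with one that was more negative (33.6% and, with TMM factors, 48.0% more positive). Ccl22, Tnfrsf9 and Ccr7 were more positive, with differences of 2.94 ± 0.13, 2.45 ± 0.19 and 1.76 ± 0.11 log2 units (SE; limma adjusted p = 7.65e-12, 1.54e-08 and 4.92e-10). Ccl2 and Il1rn were more negative, at -3.55 ± 0.18 and -3.16 ± 0.11 (limma adjusted p = 4.84e-11 and 1.67e-13). The difference was not called for Nos2 and Il6 (limma adjusted p = 0.495 and 0.555), although Il6 was at adjusted p = 0.0323 when only these 4 groups were fitted. Of 36 cell cycle genes 1 was higher, 22 were lower and 13 were not called (1 and 25 adjusted over the list alone, camera adjusted p = 3.28e-06, or 0.00778 with an estimated correlation). Of 20 p53 targets 7 were higher, 1 was lower and 12 were not called (8 and 1 adjusted over the list alone, camera adjusted p = 0.00271, or 0.0312 with an estimated correlation).

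For M2 the response differed in 1629 genes, 815 more positive and 814 more negative in knockout cells (50.03% more positive, and 62.2% with TMM factors). Flt1 and Tgm2 were more positive by 2.33 ± 0.12 and 1.83 ± 0.14 log2 units (SE; limma adjusted p = 1.30e-10 and 6.94e-08). Siglech and Il4i1, which encodes an amino acid oxidase induced by IL-4, were more negative, at -2.31 ± 0.10 and -1.46 ± 0.28 (limma adjusted p = 3.34e-11 and 0.00276). Of 13 MHC class II presentation genes 8 were higher, 1 was lower and 4 were not called, the same adjusted over the list alone (camera adjusted p = 1.47e-06, or 0.00551 with an estimated correlation). Of the 19 genes of the integrated stress response and unfolded protein response 11 were higher, 1 was lower and 7 were not called (12 and 3 adjusted over the list alone, camera adjusted p = 3.52e-09, or 0.00487 with an estimated correlation). Most members of this list were already lower in knockout cells without stimulation, which enters this difference. Of 36 cell cycle genes 1 was higher, 14 were lower and 21 were not called (1 and 25 adjusted over the list alone, camera adjusted p = 9.90e-09, or 0.00359 with an estimated correlation). Of 48 interferon-stimulated genes 2 were higher, 20 were lower and 26 were not called (2 and 27 adjusted over the list alone, camera adjusted p = 2.81e-09, or 0.198 with an estimated correlation), in a comparison that uses the same M2 control libraries. Arg1 was not called in this difference, at -0.44 (limma adjusted p = 0.766). That value subtracts a knockout effect of 1.87 without stimulation, which rests on low TPM and which carry-over of reads may account for. Under M2 itself the mean of Arg1 was higher in knockout cells, though not called in the model of all groups.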

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

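For the patterns below, 4 tests were chosen only after the result was seen: carry-over into Il4i1, H2-Ab1 and Cxcr4, deeper sequencing of M1 knockout library 3, loss of a segment gene by gene, and gain or loss of whole chromosomes.

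The response to M1 differed between genotypes, by the test of the difference itself, in 4161 genes, and the response to M2 in 1629. Genotype was reassigned within each condition in 100 ways, and with the real one included 2 of them for M1 and 3 for M2 called as many genes. Draws that mix genotypes within a group put the knockout effect into the spread between its libraries, so few calls there do not show that the responses differ. The highest other counts were 5336 and 3787, both from swaps of all 3 libraries under stimulation and none without, which turn the difference into a sum of knockout effects, and the other as high for M2, 1699, came from 3 libraries swapped under M2 and 1 without stimulation. For each of the 7 comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05, and 1 of the 10, the real one, called as many genes. The real counts were 10290 and 7557 for M1 and M2 in control cells, 2217, 5811 and 3570 for the knockout at M0, M1 and M2, and 10430 and 8414 for M1 and M2 in knockout cells, against highest others of 0, 1, 1, 1, 3, 0 and 0. Here too, splits that mix the groups put the effect into the spread between libraries, so their low counts lend no support.

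Genes whose M1 response was more positive in knockout cells, as the difference in log2 units, were Ccl22 (2.94), Ghrh (2.87), Tnfrsf9 (2.45), Il1r2 (1.95), Aplp1 (1.91), Gpr132 (1.81), Ccr7 (1.76), Msr1 (1.74), Dcstamp (1.60), Idi1 (1.24), Ocstamp (1.02), Il1b (0.99) and Cd86 (0.55). More negative were Ccl2 (-3.55), Il1rn (-3.16), Stfa3 (-3.01), Plk2 (-2.85), Arg1 (-2.37), Ccl12 (-2.30), S100a8 (-2.29), Slc40a1 (-2.18), Qprt (-2.05), Gpnmb (-1.82), Fpr2 (-1.35), Prdx1 (-1.31), Ccnb1 (-1.17), Il10 (-0.86), Tnf (-0.41) and Kdm7a itself (-0.38). Ccl22, Ghrh, Il1r2, Aplp1, Ccr7, Ccl2, Stfa3, Ccl12 and Fpr2 were listed at 0 in all unstimulated control libraries, so their differences depend on the pseudocount. Msr1, Cd86 and Kdm7a were lower and Qprt and Aplp1 higher in knockout cells already without stimulation, which enters their differences. Cd86 also stayed lower in knockout than in control cells under M1, despite its more positive response. With a pseudocount of 0.1 TPM the difference of Il1b shrank to 0.067 (adjusted p = 0.967) and that of Kdm7a to -0.28 (0.0540). S100a8, at -2.47, and Il10, at -1.21, lost the call without a smaller difference (adjusted p = 0.0658 and 0.144). That of Arg1 was lost at adjusted p = 0.0525 to 0.0674 without library 2 or 3 of unstimulated control, M1 control or unstimulated knockout cells or library 3 of M1 knockout cells, at 0.0695 when only these 4 groups were fitted and at 0.0836, with a difference of -1.94, without M2 control library 2 and M1 knockout library 3. It includes the level of Arg1 in unstimulated knockout cells, 0.59, 4.83 and 6.58 TPM against 0.34, 0 and 0.07 TPM in control cells, an excess that carry-over of reads may account for (0.450 times the median share of other genes).

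Genes whose M2 response was more positive in knockout cells were Flt1 (2.33), Cystm1 (2.16), Anpep (2.01), Msr1 (1.96), Ccl4 (1.94), Tgm2 (1.83), AA467197 (1.80), Dhrs9 (1.77), H2-Eb1 (1.63), H2-Aa (1.54), H2-DMb1 (1.47), Ccl3 (1.43), H2-DMb2 (1.35), Itgax (1.20) and Plaur (1.01). More negative were Siglech (-2.31), the small nucleolar RNA gene Snora65 (-1.91), Serpina3g (-1.56), Spsb1 (-1.55), Cp (-1.49), Il4i1 (-1.46), Cxcr4 (-1.44), Kmo (-1.20) and Cxcl10 (-1.06). Anpep and H2-Aa were listed at 0 in all unstimulated control libraries and Snora65 in all M2 knockout libraries, so the pseudocount enters their values. Msr1 was lower and Il4i1 and Cxcr4 were higher in knockout cells already without stimulation, which enters their differences. The difference of H2-Aa shrank to 0.31 and was not called with a pseudocount of 0.1 TPM (adjusted p = 0.770).

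Lists whose members differed together by camera in the M1 response are given with their median difference and the adjusted p with an estimated correlation. They were the M2-associated genes (0.13, adjusted p = 0.227), NF-kappaB targets (0.13, adjusted p = 0.206), glycolysis (0.047, adjusted p = 0.464), cell cycle (-0.33, adjusted p = 0.00778), p53 targets (0.15, adjusted p = 0.0312) and the stress response (0.29, adjusted p = 0.145). The others were NRF2 targets (-0.43, adjusted p = 0.0553), HIF targets (0.19, adjusted p = 0.228), cholesterol synthesis (0.14, adjusted p = 0.181), lysosome (-0.33, adjusted p = 0.205), osteoclast markers (0.40, adjusted p = 0.198) and replication-dependent histones (0.74, adjusted p = 0.145). With TMM factors camera lost the M2-associated genes (adjusted p = 0.0724) and the histones (0.0757). In the M2 response they were the M2-associated genes (0.089, adjusted p = 0.145), interferon-stimulated genes (-0.32, adjusted p = 0.198), MHC class II presentation (0.48, adjusted p = 0.00551), NF-kappaB targets (0.011, adjusted p = 0.350), histone modifiers of H3K9, H3K27 and H4K20 (-0.11, adjusted p = 0.487) and glycolysis (0.043, adjusted p = 0.464). The others were oxidative phosphorylation (-0.072, adjusted p = 0.354), cell cycle (-0.24, adjusted p = 0.00359), the stress response (0.22, adjusted p = 0.00487), lysosome (0.15, adjusted p = 0.145), macrophage identity (0.11, adjusted p = 0.198) and immediate early genes (0.12, adjusted p = 0.293). The NF-kappaB call was lost with TMM factors (adjusted p = 0.0519).

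Stimulated genes appeared at low levels in libraries of other conditions. The excess of Arg1 in unstimulated knockout libraries was 0.0762% of its M2 knockout level, 0.450 times the median share of the 7 other genes near 0 in unstimulated control and high in M2 knockout cells, so carry-over of reads from M2 libraries may account for it. Il4i1, H2-Ab1 and Cxcr4 stood at 3.59%, 9.75% and 11.6%, the lowest of them 21.2 times that median, which argues against carry-over for these 3 and leaves a higher level in knockout cells as a hypothesis. In M2 control library 2, 87.5% of the M1-only genes (14 of 16) lay within 3-fold of 1 common share, 0.153% of their M1 level, so carry-over from M1 libraries may account for M1 genes there. That share was 0.0788% in M2 control library 1 and 0.00853% in library 3, and whether reads or RNA were carried over was not tested.

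M1 knockout library 3 held 16 coding genes at 1 TPM or more that were listed at 0 in the other 2 libraries of its group, 5.33 times the highest such number, 3, among the other 17 libraries. It also had the fewest genes listed at 0, 10269 against 10748 to 11071, so deeper sequencing cannot be told apart from other sources, because depth is unknown. Of 22 mesenchymal genes 45.5% (10) were highest in this library by 3-fold or more, between the bounds set before, so RNA or reads from mesenchymal cells stay open too. Thy1, Postn, Fbln2 and Twist1 were listed at 0 in every library and could not be highest. Over the other genes the share lies above the upper bound, so the reading depends on which are counted. Pdgfrb stood at 1.48 TPM against 0.38 in the next library and Cdh11 at 1.12 against 0.29, but Efemp2 at 7.32 against 7.58 and Fap at 1.92 against 3.49. The mesenchymal genes named here fall outside the naming rule. No biological explanation was tested, since the other 2 libraries of the group do not share the pattern.

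In knockout cells 6 genes, Rhox5, Gpr34, Fam172a, Zfp97, Psd4 and Cacna1a (the last named after its values were seen), stood below 15% of the control mean in all 3 conditions, with control means of 2 TPM or more. For 5 of them the tested genes within 1 Mb (99 in all) had median log2 fold changes of -0.092 to 0.056 without stimulation, which argues against loss of a segment of that size. A loss stays open for Fam172a, with 1 such neighbour at -0.29, and a smaller one around Rhox5, as 1 of its 16 neighbours, its relative Rhox2d (also named after its values were seen), was lower by 2-fold or more. Medians of neighbours cannot show a loss of the gene alone or of a small segment, which stays open for all 6. The largest chromosome median in size was 0.029 over the 20 chromosomes with at least 50 tested genes (the Y chromosome, with 4, was at -0.058), which argues against gain or loss of whole chromosomes. A difference between the 2 lines that does not come from Kdm7a cannot be told apart from an effect of the knockout. Only 1 knockout line and 1 control line were named, so this holds for these 6 genes and for every other difference between genotypes.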

How the results depend on the processing

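The scaling by median ratios, the scaling alternatives for the lists, and the fit without M2 control library 2 and M1 knockout library 3 were chosen only after the data had been seen. In every alternative run the 9 gene counts stayed within 1.5 times their values, by a factor of at most 1.31, with 15 settings each and 21 for the 2 differences. From the lowest to the highest setting they ran from 9266 to 11315 and 6985 to 7756 for M1 and M2 in control cells, 1697 to 2294, 5207 to 6007 and 2776 to 3771 for the knockout at M0, M1 and M2, 9375 to 11505 and 7747 to 8759 for M1 and M2 in knockout cells, and 3747 to 4471 and 1292 to 1991 for the differences. With each library left out in turn they ran, in this order, from 10122 to 10169, 7069 to 7171, 1697 to 2014, 5268 to 5335, 2776 to 3771, 10272 to 10303, 8000 to 8208, 3747 to 3982 and 1292 to 1991. Without both doubtful libraries they were 10278, 7071, 2131, 5207, 2923, 10269, 8388, 3762 and 1399. Kdm7a fell in all 45 settings of the 3 knockout comparisons, by 1.43 to 1.97 log2 units with a highest adjusted p of 1.04e-06. Of 656 results for 282 named genes, 597 kept their direction and their side of the threshold in every setting run for them, 59 did not in some, and none reversed. Results lost and gained were 9 and 1 with TMM factors, 10 and 1 with median ratios, 11 and 3 without the trend, 11 and 1 without a filter, 0 and 0 of the 625 that the 5 TPM filter tested, 19 and 1 with a pseudocount of 0.1 TPM, 17 and 0 without both libraries, and 18 and 3 with only the groups compared. Leaving out 1 library at a time lost 144 and gained 9 of 4794. With a replicate block the counts were 10287, 7503, 2207, 5751, 3530, 10429, 8410, 4141 and 1559, and 5 named results were lost and 0 gained, but equal numbers did not pair the libraries: over 8753 genes r was -0.229 to 0.241, and own numbers matched best in 3 of 9 cases. Of the 216 list tests 112 passed, against 30 with an estimated correlation, which lost 82, and 211 with fry's mixed test, which asks for change in any direction. The number was 110 with the block, 110 without both libraries, 101 with TMM factors, 101 with median ratios and 168 with fry's directional test. Fry called 6 lists opposite to camera's direction, which camera had not called: the histone modifiers under M1 in control (adjusted p = 1.57e-05) and knockout cells (2.20e-05), M2-associated genes for the knockout at M0 (0.0366), M1-associated genes for the knockout at M1 (0.00551), and dendritic cell markers under M2 in knockout cells (1.05e-07) and in the M1 difference (0.000479). The correlations between knockout effects, 0.397, 0.570 and 0.359, were 0.454, 0.665 and 0.389 over genes called in at least 1 condition and 0.406, 0.571 and 0.368 with the stricter filter. The cause of these changes was not tested. The alternative that needs raw counts was not run, and with the depth unknown no detection limit could be set.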

Other observations

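Beyond the groups above, M1 stimulation of control cells raised hypoxia and immediate early genes. Of 16 HIF targets 13 rose and 3 fell (camera adjusted p = 1.33e-04, or 0.202 with an estimated correlation). Adm, which encodes the vasodilator adrenomedullin, rose from 7.02 ± 1.5 to 91.5 ± 4.6 TPM and Ndrg1 from 77.2 ± 5.3 to 622 ± 7.1 TPM. Of 13 immediate early genes 10 rose, 2 fell and 1 was not called (camera adjusted p = 3.03e-04, or 0.190 with an estimated correlation). Ier3 rose from 49.7 ± 2.6 to 2200.2 ± 101 TPM and Zfp36, whose product destabilizes cytokine mRNA, from 44.1 ± 2.2 to 1136 ± 31 TPM. Of 19 genes of the integrated stress response and unfolded protein response 3 rose and 16 fell (camera adjusted p = 0.0244, or 0.198 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, fell from 666 ± 14 to 77.6 ± 2.2 TPM, while Atf3 rose from 50.7 ± 0.83 to 1590.2 ± 37 TPM.

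In knockout cells M2 stimulation raised macrophage identity genes in most cases. Of 22 such genes 15 rose and 7 fell (camera adjusted p = 0.0419, or 0.312 with an estimated correlation, and 0.0842 with TMM factors). Adgre1, which encodes the F4/80 antigen, rose from 28.3 ± 1.7 to 249.8 ± 11 TPM, while Mpeg1 fell from 491 ± 4.4 to 56.5 ± 4.7 TPM. Of 7 osteoclast markers 3 rose, 1 fell and 3 were not called in knockout against control cells under M1, the same adjusted over the list alone (camera adjusted p = 0.0907). The fusion gene Dcstamp stood at 6.64 ± 0.64 TPM in control and 32.3 ± 2.9 TPM in knockout cells and Ocstamp at 1.84 ± 0.23 TPM and 5.20 ± 0.83 TPM, while Car2, named after its values were seen, stood at 40.9 ± 3.8 TPM and 27.4 ± 1.5 TPM. The list of histone modifiers of H3K9, H3K27 and H4K20, which includes Kdm7a itself, did not pass camera for the knockout in any condition (adjusted p = 0.471, 0.144 and 0.0925 at M0, M1 and M2).

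The lists of lymphocyte, of granulocyte and mast cell, and of fibroblast and epithelial markers had too few tested members for a test. Of the lymphocyte markers, Cd79a reached 21.2 TPM in M2 knockout library 3 and Lck 9.14 TPM in M1 control library 3, while Ms4a1 was listed at 0 in all 18 libraries. Of the granulocyte and mast cell markers, S100a8 reached 62.0 TPM in M1 control library 2 and Kit 1.03 TPM in M1 knockout library 3, and S100a9 was listed at 0 in all 18. Fibroblast and epithelial markers stood at no more than 1.48 TPM in any library, with Dcn at 1.47 TPM and Col1a2 at 1.31 TPM in M1 knockout library 3. Most members of these lists named here were chosen after their values were seen.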
